A study of Ginkgo biloba with 2 samples.

How the data were processed

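Small RNA was sequenced from mature leaves of Ginkgo biloba, a dioecious gymnosperm tree in which female and male plants are separate. There were 2 libraries, 1 of female leaves and 1 of male leaves, and the trees were about 30 years old per the labels. Each sample had 5 processed files. The sources used here do not say whether a library came from 1 tree or from a pool. The aligner, the miRNA database, the miRNA prediction tool, the target prediction tool and any genome build are not given in the sources used here. No genome was used here, so positions in the genome were not analysed.

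The deposited level tables of known and of predicted miRNAs are named TPM in the authors' files. The deposited values were RPM (reads divided by 1 library total and scaled by the authors): in each library every value of the known table equalled a whole number of reads divided by 1 fixed total, to within 6e-05 RPM. All low values (100% of those above 0 and below 60 RPM) were whole multiples of 1 read to within 0.01 read. The authors' second table of known miRNAs gave raw read counts per name, as deposited, beside 1 sequence, and these counts gave the same library totals, 13193290 reads for the female and 12137619 for the male library. How that 1 sequence was chosen, and whether the count covers it alone or all reads of the name, is not given in the sources used here. The known names carry no species prefix, arm or member letter, so each name was treated as 1 family. Names with much the same listed sequence, such as miR165 and miR166, were compared separately and not joined into 1 family. The deposited target tables, another kind of value, listed for each miRNA the number of predicted target transcripts and their identifiers, with empty annotation fields. The stated number equalled the number of listed identifiers in every row (0 differences).

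One read was worth 0.0758 RPM in the female and 0.0824 RPM in the male library. A known name at 0 was given an upper limit of 3 reads, 0.227 and 0.247 RPM. Fold bounds from this limit lie above the low end of the exact interval, which for miR3704 was 3821-fold against a bound of 4699-fold. The lowest value above 0 in the table of predicted miRNAs was 5 reads in both libraries, which points to a minimum in that table, so no fold, interval or limit was computed for predicted names at 0. Such names entered counts and ranks only through log2 of the values plus 1. Ratios of known names carry exact 95% intervals (conditional binomial, Clopper-Pearson) from the reads. These intervals and limits cover counting error only, since the reads are PCR products without molecular identifiers. With 1 library per sex there is no replicate, so no p-value between the sexes was computed, and no interval includes the spread between trees.

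The design was fixed before the data were examined. Names at 10 or more RPM in at least 1 library were compared as log2 of (female value + 1) over (male value + 1), a scale that understates the difference of low names, and names at least 2-fold apart were counted. Families were grouped in 13 lists fixed in advance: functional lists after the textbook targets of each family, lists of families described in conifers, monocots, mosses or algae, and a list of animal families. A list's median was placed among 10000 random lists of the same size, each member drawn from the 20 names nearest to it in mean level. Named miRNAs were the 10 with the highest mean level, the 8 with the largest ratio in each direction, and up to 4 of each list with the highest mean level. Predicted miRNAs were the 3 highest and the 3 with the largest ratio in each direction, matched by name, since both tables use the same 188 names. For targets, the rule was up to 5 targets named by most miRNAs in each library. Public nucleotide records among them are not named here.

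The alternatives were another pseudocount (0.1 or 10), no minimum or a minimum of 100 RPM, scaling by the median ratio or by the total over known names, and a 1.5-fold threshold. Alternatives chosen after the data were examined were names with the same listed sequence in both libraries (alone, or with the median ratio scaling or a pseudocount of 10), contained sequences counted as the same, names without animal-like sequences, read intervals wholly beyond 2-fold, an exact binomial test of the reads of these 2 libraries with Benjamini-Hochberg adjustment, which compares these libraries and not the sexes, and predicted names above 0 in both libraries. So was scaling of the list medians by the median ratio. The procedure was tested on simulated data: with Poisson reads for the 723 names at their mean levels, all 39 names changed 4-fold and all 21 changed 8-fold that reached the minimum were called in the right direction, 0 of 156 unchanged names were called, and the interval held the true fold for 97.7% of 216 names. The simulated reads varied by counting error only, without any spread between libraries or trees. The simulation thus checks the calculation and gives no rate of false calls for real libraries. Sequences were compared by their longest shared stretch (16 bases or more) and by the number of edits with free ends. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.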

Results

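The series addressed which microRNAs (miRNAs), short RNAs that guide the cleavage or repression of target transcripts, are present in Ginkgo leaves and how their levels compare between female and male trees. The female library held 13193290 reads and the male library 12137619. Reads of known miRNA names made up 18.7% of the female library (exact 95% interval 18.68 to 18.72%) and 20.2% of the male library (20.14 to 20.18%). Reads of predicted miRNAs made up 1.5% and 1.43%. There was 1 library per sex, so every comparison below is between these libraries, without a replicate check.

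Leaves of both sexes were dominated by miR166, the family that targets class III HD-ZIP transcription factors of leaf polarity. It stood at 86581 RPM (reads scaled to the library total) in the female and 84277 in the male library, which was 46.3% and 41.8% of all known miRNA reads, and it was listed with the sequence TCGGACCAGGCTTCATTCCCC in both. The next most abundant names were miR1215 (20053 female and 24472 male RPM), miR535 (9384 and 11552), miR5301 (7837 and 7088) and miR1083 (5964 and 6918, a difference whose direction turned with scaling by the median ratio). The 10 most abundant names by mean level also included miR6118 (2697 and 3058, turning likewise), miR1220 (2916 and 2136), miR1314 (1882 and 3136) and miR168 (2107 and 2477), the regulator of an ARGONAUTE protein. The remaining one, miR5338, was abundant in the male library alone. The highest 10 names of each library took 77.4% of the known miRNA reads in the female and 76.3% in the male library. Of 723 names, 530 were found in the female library and 532 in the male library, and 339 were found in both. Many were near the detection limit: 123 female and 146 male names had 1 to 3 reads, and at 10 or more RPM there were 170 and 179 names, 117 of them shared.

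The most abundant family, miR166, was near equal between the libraries, while miR156 was higher in the female and miR172 in the male library. Among 232 names at 10 or more RPM in at least 1 library, 68 were at least 2-fold higher in the female library, 77 were at least 2-fold higher in the male library and 87 lay within 2-fold. With scaling by the median ratio these became 73, 70 and 89, so which library had more such names turned. The intervals of the read ratio lay wholly beyond 2-fold for 66 names higher in the female and 75 higher in the male library. Names with different listed sequences were more often at least 2-fold apart. A name with few reads in one library may have another sequence listed there for that reason. Of 96 names with the same listed sequence in both libraries, 7 were at least 2-fold higher in the female and 19 in the male library (27.1% together; 11 and 15 with scaling by the median ratio), against 27 and 29 of 73 names with different sequences (76.7%). The other 63 names were at 0 in one library. Over the 117 names at 10 or more RPM in both libraries, the median log2 female over male ratio was -0.23, and the ratios given here are not corrected for it.

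**Figure D1:**
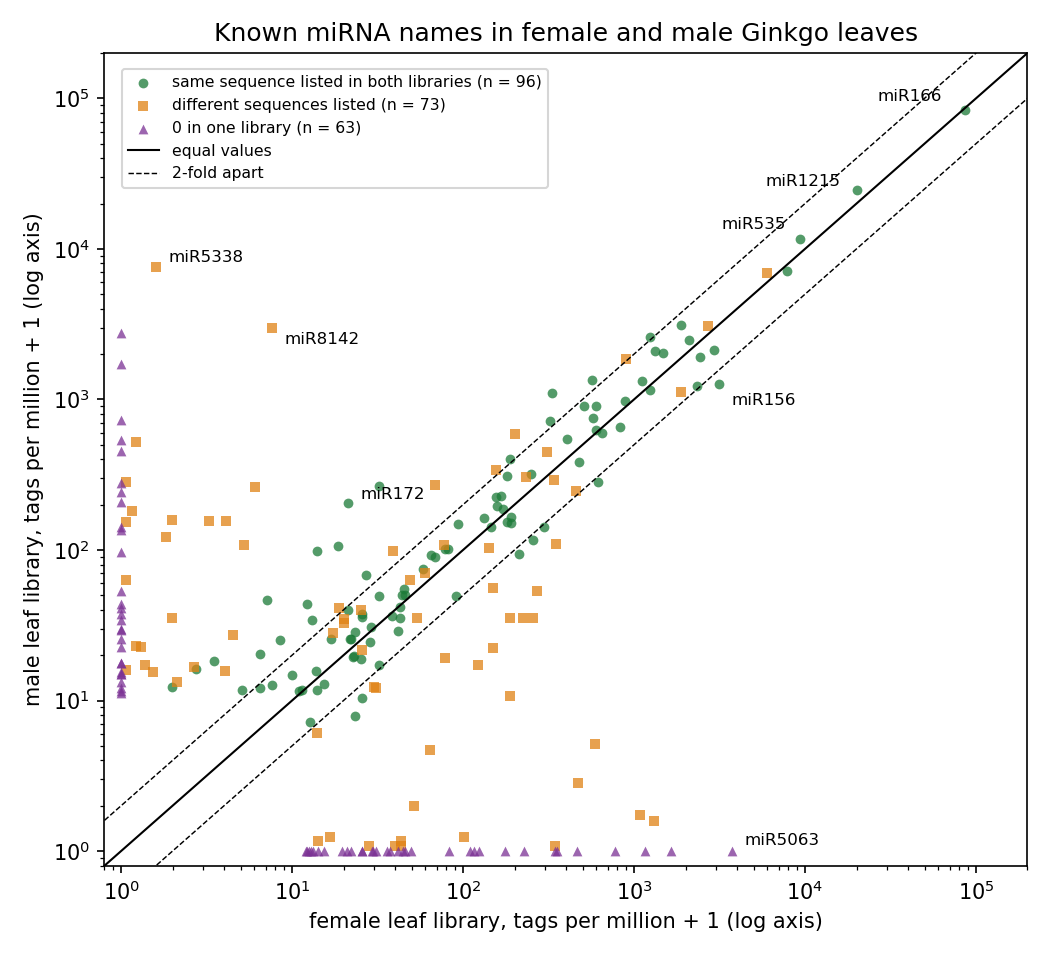
Known miRNA names at 10 or more RPM in at least 1 library, with the female library on the x axis and the male library on the y axis, both in RPM plus 1 on log axes. Each point is a name, coloured by whether the same sequence was listed in both libraries. The 96 names with the same sequence lie mostly between the dashed 2-fold lines, while the 63 names at 0 in one library lie along the axes.

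Ranked by log2 of (female value + 1) over (male value + 1), which holds back names near 0, the names with the largest excess in the female library were miR5063, miR5386, miR3704, miR6108, miR5786, miR6462, miR5517 and miR5067. The highest, miR5063, had 3745 RPM in the female library and no read in the male library, which made it at least 15150-fold higher against a limit of 3 reads. Likewise miR5386 (1646 RPM) was at least 6661-fold higher, miR3704 (1161 RPM) at least 4699-fold, miR5786 (778 RPM) at least 3147-fold, miR5517 (465 RPM) at least 1881-fold and miR5067 (353 RPM) at least 1429-fold. miR6108 and miR6462 had 7 and 9 male reads and were 2261-fold (interval 1097 to 5625) and 1470-fold (774 to 3215) higher. These last names, the only ones of the 8 with reads in both libraries, had different listed sequences.

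By the same rank, not that of the read ratios, the names with the largest excess in the male library were miR5338, miR5766, miR6460, miR5231, miR6477, miR5163, miR394 and miR8142. miR5338 had 92590 male reads (7628 RPM) and 8 female reads, and miR8142 had 36290 male reads (2990 RPM) and 87 female reads. The male sequences listed for these names were within 1 and 2 edits, respectively, of the animal miRNA let-7a, and the female sequences were not. miR5766 (2771 RPM), miR6460 (1727), miR5231 (725), miR6477 (535) and miR5163 (454) had no female read. Against a limit of 3 reads they were at least 12186-fold, 7594-fold, 3187-fold, 2353-fold and 1996-fold higher in the male library. The miR5163 sequence was 4 edits from let-7a. miR394, which targets an F-box transcript, had 3 female and 6365 male reads, a ratio of 2306 (interval 789 to 11186). Its listed male sequence was 4 edits from the reverse complement of the female one and 10 edits from the female sequence itself.

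Among the phase change and flowering families, miR156 and miR172 differed in opposite directions. miR156, which targets SPL transcription factors and marks the juvenile phase in flowering plants, stood at 3144 RPM in the female and 1259 in the male library, 2.50-fold higher in the female (interval 2.45 to 2.55). miR172, which targets AP2-like transcription factors and marks the adult phase there, stood at 20.2 and 203 RPM, higher in the male library with a log2 ratio of -3.26 (interval of the male over female ratio 8.83 to 11.4). miR529, which also targets SPL transcripts, was 1.93-fold higher in the female library (1.89 to 1.96), miR535 was 1.23-fold higher in the male library (1.22 to 1.24) and miR157 stood at 42.8 and 49.5 RPM. All 5 had the same listed sequence in both libraries, TGACAGAAGAGAGTGAGCAC for miR156 and AGAATCTTGATGATGCTGCAT for miR172. So 1 of 5 families was at least 2-fold higher in each direction, or 2 in the female library with scaling by the median ratio, where miR529 passed 2-fold (log2 1.18). The list's median log2 ratio of -0.20 lay at percentile 57.4 of random lists and turned to 0.02 when the values were scaled by the median ratio.

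In the leaf growth list, no family at 10 or more RPM was at least 2-fold higher in the female library and 2 of 4, miR164 and miR396, were higher in the male library. With scaling by the median ratio both lay within 2-fold (log2 -0.93 and -0.82). miR164, which targets NAC transcription factors of leaf margins and organ boundaries, was 2.23-fold higher in the male library (interval 2.15 to 2.32), at 323 and 721 RPM. miR396, which targets growth-regulating factors, was 2.07-fold higher (2.02 to 2.11), but its listed male sequence was 3 edits from the reverse complement of the female one, the relation expected of opposite arms of a hairpin. miR166 differed by 1.03-fold and miR165, which shares a stretch of at least 16 bases with it, by 1.15-fold, both higher in the female library. The list's median log2 ratio was -0.65, at percentile 19.2, and -0.25 over the 5 families with the same listed sequence. In the auxin list only miR167, which targets auxin response factors, reached 10 RPM. It was 2.97-fold higher in the male library (2.84 to 3.10), again with listed sequences 4 edits from each other's reverse complement. miR390, which triggers small RNAs against auxin response factors, had 19 female and 76 male reads, miR160 had 55 and 31, and miR393, directed at auxin receptors, had 5 and 1. Only miR390, 1 of the 4 families, had the same listed sequence in both libraries. The listed sequences of miR160 and miR393 were 10 and 9 edits apart, and 5 and 6 edits from each other's reverse complement. The median of this list was -0.61, at percentile 23.8.

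Families with other transcription factor targets split. Of the families that target GRAS and NF-Y factors, miR169 was 2.08-fold higher in the male library (interval 2.04 to 2.12) with the same listed sequence in both, but lay within 2-fold with scaling by the median ratio (log2 -0.83). miR171 stood at 57.5 and 73.2 RPM. miR170 had 357 female reads and 1 male read, with listed sequences 1 edit apart, a ratio of 328 with an interval of 58.6 to 13008. The median of this list was -0.34 (percentile 53.0) while its mean was 1.10, which rests on miR170. Of the families that target MYB factors, none of the 2 at 10 or more RPM was 2-fold apart: miR858 was 1.58-fold higher in the male library (1.47 to 1.70), and miR159 had 172 and 130 reads (female over male 1.22, 0.964 to 1.54). miR319 and miR828 had at most 34 reads. The median of this list was 0.01 and its mean -0.08 (percentile 59.6 of the median).

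The small RNA machinery families that reached 10 RPM, miR162 and miR168, were near equal. miR162, which targets the Dicer-like enzyme that makes plant miRNAs, had 550 and 497 reads (female over male 1.02, interval 0.900 to 1.15), miR168 was 1.18-fold higher in the male library (1.16 to 1.19) and miR403 had 3 female reads and no male read. The median of the list was 0.03 (percentile 44.5), and -0.10 over miR162 and miR168 alone. Of 6 nutrient and copper families at 10 or more RPM, 5 lay within 2-fold and 1 was higher in the male library, miR2111 (1.14 and 12.2 RPM, different listed sequences), which was picked out after its value was seen and lay just within 2-fold with a pseudocount of 10 (log2 -0.99). With scaling by the median ratio miR395, also picked out afterwards, passed 2-fold (log2 1.02), higher in the female library. miR397, which targets laccases, was 1.27-fold higher in the female library (1.25 to 1.29). miR408, which targets copper proteins, stood at 44.7 and 49.2 RPM, a difference whose direction turned with scaling by the median ratio. miR857 was 1.42-fold higher (1.23 to 1.65) and miR398, a regulator of copper superoxide dismutase, 1.77-fold higher (1.51 to 2.08) in the male library, miR398 with listed sequences 2 edits apart. The median of the list was -0.25 (percentile 47.7), 0.10 over the 6 families with the same listed sequence and -0.0662 with scaling by the median ratio.

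Of the families directed at NBS-LRR disease resistance genes, miR482 was 1.32-fold higher in the male library (interval 1.28 to 1.36) and miR2118 stood at 145 and 142 RPM. The 2 families beyond 2-fold, both higher in the male library, were miR1448 (41 and 1879 reads, 49.8-fold, 36.6 to 69.6) and miR472 (13 and 420 reads, 35.1-fold, 20.3 to 66.5), each with listed sequences 3 edits apart. In the female library the sequence of miR472 shared a stretch of at least 16 bases with that of miR482. There, the sequence of miR1448 shared such a stretch with that of miR8036. The median of the list was -0.40 (percentile 31.1).

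**Figure D2:**
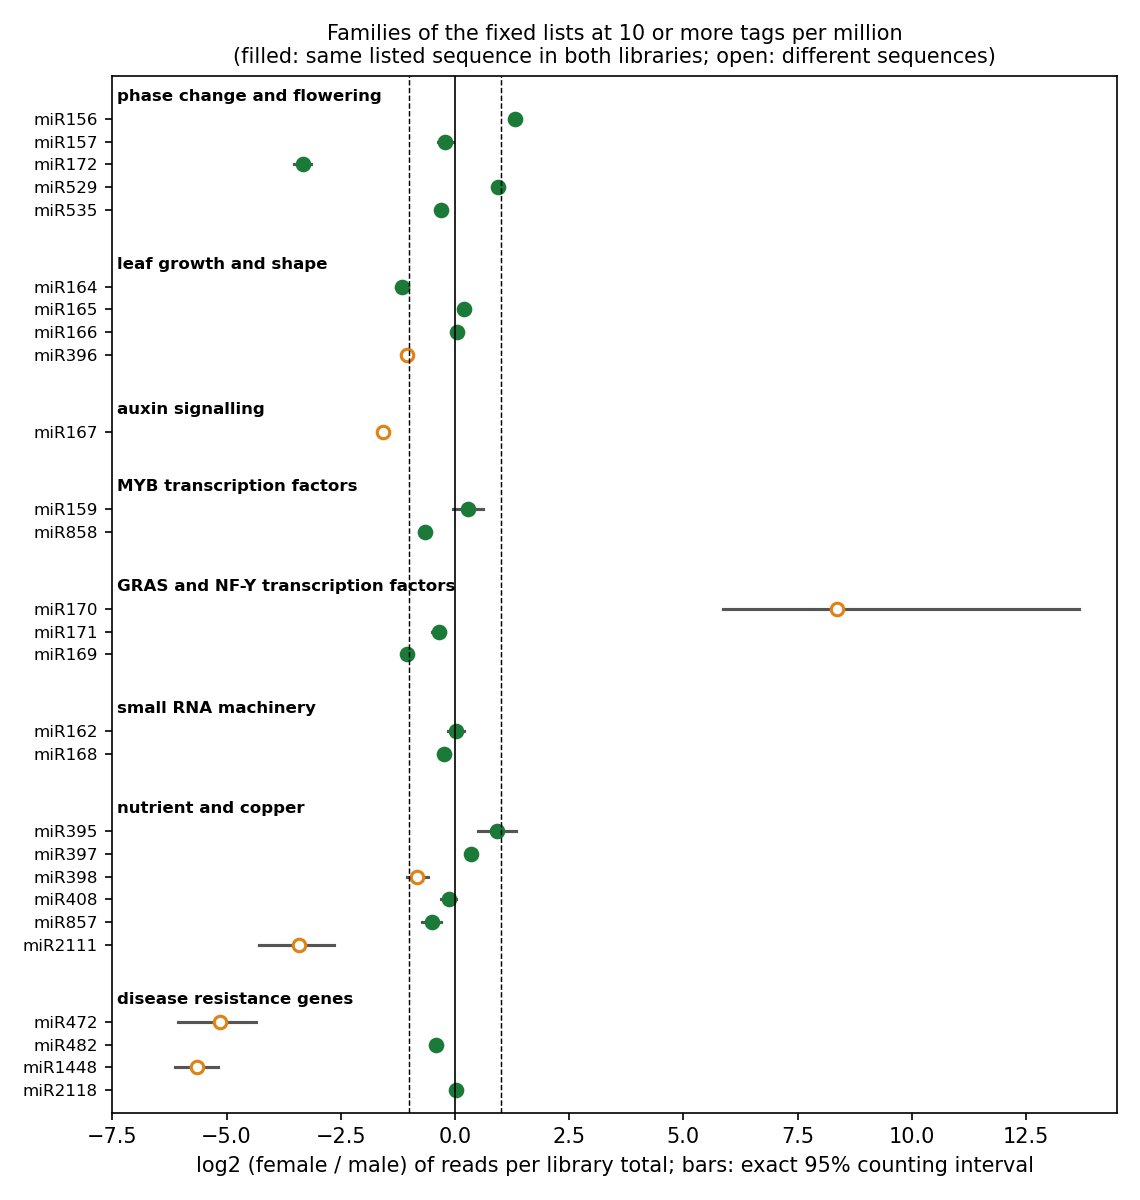
Female over male ratio of the families of the functional lists that reached 10 RPM, as log2 of reads per library total on the x axis, with exact 95% counting intervals as bars. Filled points had the same listed sequence in both libraries and open points had different sequences. miR156 and miR172 lie on opposite sides of 0, and the widest ratios, of miR170, miR1448 and miR472, are open points.

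The lists of families described in particular plant lineages do not cover every such family. Their counts and medians describe the listed names only, and names outside the lists may differ. Of 24 conifer or gymnosperm families, 10 were in the tables. miR1314 was 1.67-fold higher in the male library (interval 1.64 to 1.69) and miR1310 was 1.94-fold higher in the female library (1.63 to 2.31; past 2-fold with scaling by the median ratio, log2 1.13), each with the same listed sequence in both, whereas miR3704 and miR952 (376 reads, at least 115-fold) had female reads only. Their median was 0.29 (percentile 94.9), or 0.0431 with a pseudocount of 10. Of 6 monocot families, 5 were present with none at 10 RPM. miR437 had 26 and 32 reads, miR528 11 and 9, miR444 0 and 7, and miR1432 0 and 1, and the median was -0.11 (percentile 24.1). Of 10 moss families, 5 were present, with a median of -1.84 (percentile 4.25), or -0.61 with a pseudocount of 10. miR1030 was 3.82-fold higher in the male library (3.18 to 4.62) with the same listed sequence in both, miR537 had 442 male reads only, miR1023 had 9 and 77 reads and miR902 had 122 and 3. In the male library the sequence of miR1030 shared a stretch of at least 16 bases with that of miR530. Of 36 algal families, 8 were present. miR1154 (246 reads) and miR1162 (173 reads) had female reads only, miR1160 had 8 and 26, and miR916 had 19 and 11, each with different listed sequences. Their median was 0.55 (percentile 98.0), or 0.91 with absent names at their bound and 0.0821 with a pseudocount of 10. None of the 28 animal family names was in the tables.

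The predicted miRNAs novel_mir_93 and novel_mir_88 were the highest in both libraries. novel_mir_93 stood at 4036 RPM in the female and 4025 in the male library, novel_mir_88 at 2273 and 3264 (1.44-fold higher in the male library, 1.41 to 1.46) and novel_mir_61, highest after these by mean level but not within either library, at 876 and 1014. Of 188 names, 103 were listed above 0 in the female and 99 in the male library, with 55 in both and 41 in neither. Across the 55 shared names the log2 levels correlated with r = 0.96 and Spearman's rho = 0.95, where names are not independent replicates. Of 57 names at 10 or more RPM in at least 1 library, 24 were at least 2-fold higher in the female library by log2 of the values plus 1. Another 11 were higher in the male library and 22 lay within 2-fold. Most of the names beyond 2-fold were listed at 0 in one library: among the 34 listed above 0 in both, 8 and 4 were beyond 2-fold. Names from novel_mir_1 to novel_mir_103 all had female values, and those from novel_mir_104 to novel_mir_147 had male values only. Whether a 0 in this table is a measured level is therefore not known. By log2 of the values plus 1, the names with the largest female excess were novel_mir_22 (760 RPM), novel_mir_78 (422) and novel_mir_33 (293), each listed at 0 in the male library. Those with the largest male excess were novel_mir_138 (395 RPM), novel_mir_124 (218) and novel_mir_115 (177), each listed at 0 in the female library.

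Of 339 names found in both libraries, 151 had an identical sequence (44.5%). In another 19 one sequence was contained in the other, in 26 the sequences were within 2 edits, and in 143 they were further apart. The 151 names carried 83.9% of the known miRNA reads in the female and 81.4% in the male library. A 21-base sequence, the usual length of plant miRNAs, was listed for 295 of 530 female and 301 of 532 male names, and names whose sequence began with T (U in RNA) carried 87.7% and 89.8% of the reads. Stretches of at least 16 bases were shared by 11 pairs of names in the female and 16 pairs in the male library, with miR165 and miR166 among them, so the split of reads within such pairs is uncertain.

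The target lists are predictions from the miRNA sequences, not measurements, so they follow the listed sequences by construction. Targets were listed for 380 known names in the female and 340 in the male library, with a median of 3 per name in both. There were 2415 distinct miRNA and target pairs in the female library and 2351 in the male library, of which 884 were shared (Jaccard index 0.228). For the 110 names with the same listed sequence and any target, all 110 target lists were identical. For 89 names with different sequences and targets in both libraries, 11 lists were identical. Thus miR156 had 13 predicted targets and miR172 had 8 in both libraries, while miR396 had 10 in the female and 13 in the male library and miR1448 had 1 and 23. The 5 targets named by most known miRNAs were public nucleotide records, named by 16 miRNAs each in the female and 21 each in the male library. Among assembled leaf transcripts, CL2141.Contig2 was named by 8 female and 4 male miRNAs and CL249.Contig1 by 5 in both. The target tables give predicted miRNAs their own identifiers in each library, with 155 female and 158 male entries against 103 and 99 names above 0 in the level tables. How these relate is not given in the sources used here. For these entries there were 596 and 793 distinct targets with 440 shared (Jaccard index 0.464), led by contigs of the cluster CL2091, such as CL2091.Contig10, named by 21 miRNAs in both libraries. The tables give no annotation for these transcripts.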

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

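All tests in this part, on let-7-like sequences, were chosen after the result was seen. The sequences listed beside the read counts held a signal that the comparison of levels does not use: 3 names of the male library had a sequence within 2 edits of an animal miRNA, and none of the female library had. They were miR5338 with 92590 reads and miR8142 with 36290 reads, both close to let-7a, and miR841 with 640 reads, 1 edit from miR-101.

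The 3 male names prompted the comparison with a panel of 19 animal miRNAs, in which the highest count in 100 sets of shuffled male sequences was 0. Because those names prompted the comparison, it is no independent test of chance, and it does not give the source of the resemblance. The names miR5338 and miR8142 together held 95 female reads, while a hundredth of the male level would give 1401. If a count covers all reads of its name, this argues against a Ginkgo sequence transcribed alike in both trees. If a count covers its listed sequence alone, it cannot decide this, because the female sequences listed for these names are not let-7-like. Reads from an animal and a sequence transcribed in the male tree alone cannot be told apart, because no genome was searched. The male reads counted under miR5338 and miR8142 came to 10618 RPM, or 1.06% of the male library. Without the 3 names, 74 names instead of 77 were at least 2-fold higher in the male library.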

How the results depend on the processing

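The settings with the same listed sequence (alone or with another choice), contained sequences, no animal-like sequences, read intervals beyond 2-fold, the exact test on reads and predicted miRNAs above 0 in both libraries were chosen after the data were seen. So was scaling of the list medians by the median ratio. No paired analysis was possible because there was 1 library per sex. For the 66 named known miRNAs, 261 of 264 values under another pseudocount or scaling kept their direction. Another pseudocount cannot turn a direction, nor can scaling for a name at 0 in one library, so this count shows little. The 2-fold calls of these miRNAs can change: with scaling by the median ratio 27 of 30 were kept. With it miR164 (-0.93), miR396 (-0.82) and miR169 (-0.83) were lost, and miR529 (1.18) and miR1310 (1.13) were gained. Over all compared names that scaling kept 138 of 145 calls and gained 5, and a pseudocount of 10 kept 132. The 3 values whose direction turned, all with scaling by the median ratio, were miR1083 (-0.21 to 0.02), miR408 (-0.13 to 0.09) and miR6118 (-0.18 to 0.05). The counts of 68 and 77 known names at least 2-fold higher in the female and the male library became 117 and 132 with no minimum, 32 and 34 with a minimum of 100 RPM, and 7 and 19 with the same listed sequence only (11 and 15 with the median ratio scaling added, 5 and 14 with a pseudocount of 10 added). With that scaling alone they were 73 and 70, which turned the balance. Another minimum or the same listed sequence only, by construction, tests another number of names. The exact test on reads called 93 and 125 names, since it has no fold threshold. Names found in the female, the male and both libraries numbered 292, 297 and 193 at 1 or more RPM and 170, 179 and 117 at 10 or more, so the number of rare names rests on very few reads. Predicted miRNAs beyond 2-fold numbered 37 and 23 with no minimum, and 8 and 4 among names above 0 in both libraries. With the median ratio scaling the list medians became 0.0199 (phase change), -0.12 (GRAS and NF-Y), 0.25 (small RNA machinery), -0.17 (disease resistance), 0.38 (conifer), -0.10 (monocot), -0.0662 (nutrient and copper) and 0.19 (MYB). With the same listed sequence only they became -0.25 (leaf growth), -0.70 (GRAS and NF-Y), -0.19 (disease resistance), 0.28 (conifer) and -0.11 (monocot), and with a pseudocount of 10, 0.0431 (conifer), -0.0118 (monocot), -0.61 (moss), 0.0821 (alga), -0.29 (leaf growth), -0.23 (auxin) and -0.0939 (nutrient and copper). The cause of these moves was not tested. Identical listed sequences made up 63.8% of shared names with 10 or more reads in both libraries, and 50.1% when contained sequences counted as the same. The Jaccard index of known targets was 0.256 by target alone. The highest member of each family was not run, because each name was treated as 1 family.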

Other observations

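The tests of sequence, naming, sparse sampling, scaling and shared reads in this part were chosen after the results were seen. The names singled out below for a shared sequence were also chosen after their values were seen.

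Where the same sequence was listed in both libraries, 26 names differed at least 2-fold, of which 22 did with scaling by the median ratio, which also added 4 higher in the female library (miR529, miR1310, miR395 and miR5275), and 19 with a pseudocount of 10. Besides miR156, the names higher in the female library were miR2199 (612 and 282 RPM), miR6300 (296 and 141), miR6190 (257 and 116), miR5813 (212 and 93.2), miR5227 (24.7 and 9.47) and miR5138 (22.2 and 6.84). Besides miR172, miR1030, miR164 and miR169, the most abundant names higher in the male library were miR5261 (565 and 1344 RPM), miR1521 (329 and 1109), miR1526 (186 and 399) and miR7539 (31.2 and 266). With scaling by the median ratio, miR164 (log2 -0.93), miR169 (-0.83) and miR1526 (-0.86) lay within 2-fold. With a pseudocount of 10, miR5227 (0.83) and miR5138 (0.94) did.

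Large differences went with different sequences under one name. Of names with different listed sequences 76.7% were at least 2-fold apart, against 27.1% of names with the same sequence, and at 10 to 100 RPM the shares were 75% of 36 names and 23.3% of 43. A candidate explanation is that one name stands for different small RNAs in the 2 libraries. The reverse stays open too: a large difference leaves few reads in one library, where another sequence may be listed for that reason. Identical sequences made up 44.5% of all shared names and 63.8% of those with 10 or more reads in both libraries. The comparison at like mean level does not separate these. Over names at 10 or more RPM in both libraries, log2 levels correlated with r = 0.95 (83 with the same sequence) and 0.80 (34 with different sequences). For the names at 0 in one library, the tables argue against sparse sampling of names at an equal level: there were 63 among 232, and counting error alone would give 4.4e-36. That number treats reads as independent, although they are PCR products without molecular identifiers. The tables also argue against the listed sequence being listed under another name there, which was so for 1.59% of these names (1 name). Reads under a name whose listed sequence is another one, and reads without a name, stay open.

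The opposite difference of miR156 and miR172 remained with scaling by the median ratio, where their log2 ratios were 1.55 and -3.03. That scaling moves the log2 ratios of abundant names by about the same amount. The outcome thus followed from the deposited ratios and is no separate test of a shift as the cause. A larger shift between the libraries was not tested. Reads moved between the similar names miR156, miR157, miR529 and miR535 cannot be ruled out for miR156. The summed level of these names was 14920 RPM in the female and 14079 in the male library. That is a log2 ratio of 0.0837 as deposited and 0.31 after scaling by the median ratio. The sum cannot decide the question, because most of it was miR535 (9384 and 11552 RPM). It also leaves out miR1088, whose sequence shared a stretch of at least 16 bases with that of miR529 in both libraries. A difference between the sexes is untested, since there was 1 library per sex, and a difference in leaf age or between trees stays open with it.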
